A study of Arabidopsis thaliana with 4 samples.

How the data were processed

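Messenger RNA was measured by sequencing in 10-day-old Arabidopsis thaliana seedlings of the C24 accession. There were 4 groups, the wild type and the mutants prp31, zop1 and sta1, each with 1 library. Per the labels' protocols, seedlings grew on agar medium at 23 °C in 16 h of light and 8 h of dark, and messenger RNA was enriched from total RNA with oligo(dT) beads. Groups were taken from the titles and genotype labels. The labels name no plate, batch or sequencing date, and nothing in them says how many plants entered a library.

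The authors deposited 1 table of FPKM values (fragments per kilobase of transcript and per 1000000 mapped fragments) with 34133 loci and 1 column per library. Per the submitters' processing notes the tools were TopHat2 2.0.12, Bowtie, Cufflinks 2.0.1 and Cuffdiff and the genome build was TAIR10; their roles, order and settings are not given in the sources used here. Whether the libraries were stranded is also not given, so reads of a gene and of an overlapping antisense gene were not told apart. Close copies, such as the LHCB1, RBCS, PDF1.2 and cruciferin genes, can share reads, and their split follows the authors' processing. All 133 chloroplast and 146 mitochondrial loci were listed at 0 in every library, so an exact 0 in the table is not always a measured absence. Names, transcript lengths and positions came from the TAIR10.1 RefSeq annotation, in which 33389 loci were found; the table itself holds no positions.

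FPKM carry no read numbers, but the low values of a locus were whole multiples of what 1 read is worth. That worth, relative to the wild type library, was 0.902 in prp31, 1.21 in zop1 and 1.11 in sta1. At 746 of 2556 single-transcript loci the worth of 1 read matched an effective length of the transcript less 204 nt, which puts the totals, in units of 1000000 reads, at 49.2 for the wild type, 54.6 for prp31, 40.7 for zop1 and 44.3 for sta1. Whole reads were recovered for 16353 of 24606 loci above 0 in at least 2 libraries (66.5%). Tested on 2930 simulated loci, the step found 99.6%, of which 99.9% were right, and it accepted 0.90% of 2999 shuffled loci. A divisor shared by all libraries cannot be seen, so the read numbers are lower bounds. Reads were used only to describe depth and to give 95% intervals of a ratio of FPKM (exact binomial, on the reads of the mutant and wild type library). These intervals cover counting error only, not differences between plants or preparations.

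With 1 library per group no test across replicates was possible and no p-value is given. Values were compared as log2(FPKM + 1), which understates the change of low genes. Loci with a mean of at least 1 FPKM over the 4 libraries entered (19240 loci), and a locus was counted as higher or lower when the difference reached 1 on that scale, called the 2-fold rule here. Folds printed for single genes are ratios of FPKM. No fold is given where a library is listed at 0. On simulated reads of 2 libraries for the loci with recovered reads, 90.5% of loci changed 4-fold met the rule, as did 7 unchanged long protein-coding loci and 61 of 671 other unchanged loci. That holds for counting error alone. With the scatter between libraries described next, simulated unchanged libraries gave 149 higher and 148 lower loci per mutant, or 75.8 and 75.02 among long protein-coding genes, so many loci that meet the rule can be unchanged.

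Changes in different mutants share the wild type library. Therefore 100 sets of 3 unchanged libraries and a shared control were simulated, with scatter drawn by expression level (20 bins) from the most alike pair of mutant libraries. That pair was zop1 and sta1 over all loci, and prp31 and sta1 among long protein-coding genes. The overlap of independent lists was computed from the sizes of the lists, and the count was repeated with each mutant in turn as the reference. The scatter between libraries of different genotypes holds any real difference between them and can exceed the scatter of replicates.

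The genes named follow a rule, whose loci are in part summarised by class in the report. For each mutant they are the 10 loci with the largest rise and the 10 with the largest fall. Over the 3 mutants they are the 10 in each direction that rank highest by the smallest of the 3 differences, and for each pair of mutants the 3 largest each way. The mutated genes are always named, as are members of 22 gene lists (348 genes) that met the 2-fold rule in any mutant, or the member with the largest change where none did. The lists cover the mutated genes, cold and dehydration, abscisic acid, heat shock, the unfolded protein response, SR splicing factors, spliceosome core, gene silencing machinery, DNA demethylation, silenced loci, photosynthesis, salicylic acid and immunity, jasmonate, ribosomal proteins, root markers, seed storage and embryo markers, flowering, cell cycle, DNA damage, oxidative stress and mitochondrial retrograde response, circadian clock, and anthocyanin and flavonoid synthesis. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins; these percentiles describe these libraries and are not p-values. Other list members are named as examples, and were chosen after their values were seen.

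The comparisons, rules, lists and 5 alternatives (a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, rescaling to a sum of 1000000 per library, and median-of-ratios scaling) were chosen before the data were examined. Chosen after seeing the data were a restriction to protein-coding genes with a transcript of at least 500 nt (long protein-coding genes, 18362), the genes named by the same rule among them (over the 3 mutants, those that also met the 2-fold rule), a simulation with the scatter of prp31 and wild type, and 4 further gene lists used in the closing section, which cover higher expression in iron deficiency, iron storage, phosphate starvation, and early stress and touch. No source used here marks transposable element genes, so that planned comparison was made over 1973 loci that the table lists by a transcript identifier, of which 1971 are pseudogenes in the reference, and over 17 Sadhu retrotransposon loci named in the annotation. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.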

Results

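Transcript levels were compared between wild type C24 seedlings and 3 mutants, prp31, zop1 and sta1, with 1 library for each genotype. PRP31 and STA1 are proteins of the spliceosomal snRNPs, and ZOP1 is a zinc-finger nucleic acid-binding protein linked to pre-mRNA splicing. The series title ties PRP31 to transcriptional gene silencing and the stress response. The table held 34133 loci. Between 19066 (sta1) and 19188 (zop1) loci reached 1 FPKM in a library, and the implied depth, in units of 1000000 reads, was 49.2 in the wild type, 54.6 in prp31, 40.7 in zop1 and 44.3 in sta1. No difference has a replicate check, so values describe these libraries and not the genotypes.

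The mutated genes were examined first. PRP31 (AT1G60170, chromosome 1, 22192758 to 22195400, TAIR10.1) was at 16.4 FPKM in the prp31 library, 1.41-fold lower than the 23.2 FPKM of the wild type, and at 25.1 FPKM in zop1 and 23.7 FPKM in sta1. ZOP1 (AT1G49590, chromosome 1, 18354744 to 18356733) was at 7.99 FPKM in zop1, 1.76-fold lower than the 14.1 FPKM of the wild type, and at 12.8 FPKM in prp31 and 15.0 FPKM in sta1. STA1 (AT4G03430, chromosome 4, 1516030 to 1520563) was at 18.9 FPKM in sta1, 1.34-fold above the 14.1 FPKM of the wild type, and at 15.5 FPKM in prp31 and 15.6 FPKM in zop1. The PRP31 and ZOP1 transcripts were therefore lowest in the library of that mutant, and the STA1 transcript was highest in the sta1 library. The labels do not say where in each gene the lesion lies or whether it lowers the transcript, so the STA1 value neither supports nor contradicts the label.

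**Figure D1:**
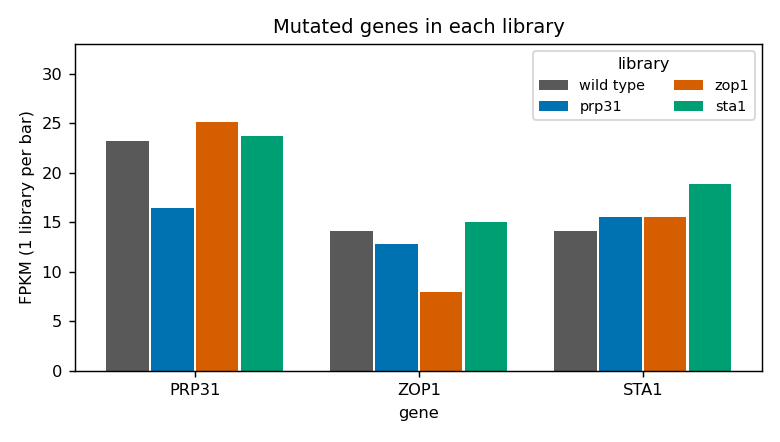
FPKM of PRP31, ZOP1 and STA1 (horizontal axis) in each of the 4 libraries, 1 bar per library and no error bars since each genotype has 1 library. PRP31 is lowest in prp31 (16.4 FPKM), ZOP1 is lowest in zop1 (7.99 FPKM) and STA1 is highest in sta1 (18.9 FPKM).

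Of the long protein-coding genes higher in prp31 than in the wild type, the uncharacterised AT4G16855 ranked highest, listed at 0 in the wild type and at 5.28 FPKM in prp31. It was above 0 in prp31 only, so its reads could not be recovered and its read support is unknown. The lipid-transfer protein gene AT4G12490 was 5.28-fold higher (95% counting interval 4.80 to 5.82), from 17.5 to 92.2 FPKM, and AT4G12500 of the same family was 4.40-fold higher (3.60 to 5.41). PEPC1 (AT1G17710) and PS2 (AT1G73010), phosphatase genes known to be induced by phosphate starvation, went from 2.82 to 13.3 FPKM and from 11.5 to 42.9 FPKM. The defensin genes PDF1.3 (AT2G26010) and PDF1.2A (AT5G44420) went from 0.978 to 5.92 FPKM and from 0.0869 to 2.04 FPKM, the latter from 1 read in the wild type. AT1G23110 and AT5G20790 were 4.14-fold and 3.18-fold higher, and AT3G25011 rested on 1 read in the wild type and 4 in prp31. Lower in prp31 were LPLAT2 (AT1G63050), a membrane-bound O-acyltransferase gene, by 5.76-fold (4.63 to 7.22), from 13.9 to 2.42 FPKM, and AT5G23840, a lipid-recognition protein gene, from 10.0 to 1.44 FPKM. PR1 (AT2G14610), the marker gene of salicylic acid signalling, was 3.66-fold lower (3.41 to 3.92), from 125 to 34.3 FPKM. AT5G59330, of the lipid-transfer protein family, was 4.25-fold lower (2.22 to 8.81), and AT3G46616 had 1 read in the wild type and is listed at 0 in prp31. LPLAT2 was at 12.5 FPKM in zop1 and 13.6 FPKM in sta1.

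By the 2-fold rule 99 loci were higher and 82 lower in prp31. Of these, 38 and 28 were long protein-coding genes, and 61 and 54 were shorter or not protein-coding. Unchanged libraries simulated with the scatter between mutant libraries gave more, 149 higher and 148 lower loci per mutant, or 75.8 and 75.02 among long protein-coding genes. But prp31 and wild type were the most alike of all pairs of libraries. Among long protein-coding genes their log2 differences had an SD of 0.206, against 0.268 for prp31 and sta1, the pair that gave the scatter. That wider scatter can hold real differences between the mutants, so counts below it do not show that prp31 is unchanged. The 10 largest rises under the rule were 5 snoRNA, 2 tRNA, 2 miRNA and 1 pseudogene loci, all listed at 0 in the wild type, and the 10 largest falls, all listed at 0 in prp31, held 5 snoRNA, 1 tRNA, 2 miRNA and 2 protein-coding loci. At such loci a few reads give a high value: AT2G20723, a snoRNA of 74 nt, was at 396 FPKM in prp31 from 8 reads. For this reason the genes named here are long protein-coding genes, a choice made after seeing the data.

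Of the long protein-coding genes higher in zop1, AT3G29633 (16.7 FPKM), AT3G04854 (8.70 FPKM) and AT3G48346 (4.08 FPKM, from 2 reads, with no change inside its counting interval), all uncharacterised, were listed at 0 in the wild type. AT3G29633 and AT3G04854 were above 0 in zop1 only, so their reads could not be recovered and their read support is unknown. BHLH100 (AT2G41240), a transcription factor gene known to be induced by iron deficiency, was at 1.08 FPKM in the wild type and 19.6 FPKM in zop1. bHLH38 (AT3G56970) and bHLH39 (AT3G56980), of the same family, were 5.91-fold (4.90 to 7.19) and 4.96-fold (3.74 to 6.68) higher. AT1G47400, AT1G47395 and AT2G30766, which encode short IRON MAN peptides, went from 1.45 to 14.5, from 6.29 to 41.7 and from 20.8 to 142 FPKM, and the uncharacterised AT2G14247 from 2.93 to 32.2 FPKM. AT5G35480 and the adjoining MRU1 (AT5G35490) were at 217 and 28.4 FPKM in zop1, against 36.6 and 4.27 FPKM in the wild type and 51.5 and 6.88 FPKM in sta1. Of the lower genes RTFL13 (AT3G23635) ranked first, at 10.5 FPKM in the wild type and listed at 0 in zop1. It was above 0 in the wild type only, so its read support is unknown too. The seed storage gene CRC (AT4G28520) went from 5.37 to 0.09 FPKM. ZAT10 (AT1G27730), a zinc-finger repressor gene, was 9.67-fold lower (7.91 to 11.9), from 33.9 to 3.51 FPKM, the mitochondrial dicarboxylate carrier gene DIC2 (AT4G24570) 10.1-fold lower (8.36 to 12.4), the deadenylase gene CAF1a (AT3G44260) 8.09-fold lower (6.81 to 9.66), the AP2/ERF-type gene AT5G51190 9.23-fold lower (7.41 to 11.6) and ERF104 (AT5G61600) 5.27-fold lower (4.53 to 6.16). AT4G13575 was at 33.9 FPKM in the wild type, 5.17 FPKM in zop1 and 32.9 FPKM in sta1.

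By the 2-fold rule 184 loci were higher and 247 lower in zop1, against 149 and 148 in simulated unchanged libraries, and 110 and 174 of them were long protein-coding genes, against 75.8 and 75.02. All 10 of the largest rises and all 10 of the largest falls under the rule were at loci that are shorter or not protein-coding, at 0 in the lower library. The long protein-coding genes with recovered reads that met the rule had a median of 489 reads (higher) and 577 reads (lower) in the 2 libraries together.

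In the sta1 library BHLH100 ranked highest of the long protein-coding genes, at 24.96 FPKM, bHLH38 was 7.72-fold higher than in the wild type (6.43 to 9.34), bHLH39 6.88-fold (5.24 to 9.17), and AT2G30766 was at 150 FPKM. AT2G04050, a MATE efflux carrier gene, was 10.2-fold higher (7.90 to 13.4), from 1.08 to 10.99 FPKM, UGT74E2 (AT1G05680), a glycosyltransferase gene responsive to oxidative stress, 7.17-fold higher (6.02 to 8.60), from 2.26 to 16.2 FPKM, and the expansin gene EXPA16 (AT3G55500) went from 2.19 to 13.7 FPKM. RTFL13 was listed at 0 in sta1, as was AT3G25011, with 1 read in the wild type. PR1 was 7.64-fold lower (6.89 to 8.49), at 16.4 FPKM, PCR1 (AT1G14880), PLANT CADMIUM RESISTANCE 1, 9.76-fold lower (7.59 to 12.7), DIC2 8.99-fold lower (7.55 to 10.8), CAF1a 7.22-fold lower (6.17 to 8.49), AT5G51190 6.25-fold lower (5.23 to 7.52) and ZAT10 5.89-fold lower (5.05 to 6.91). The nucleoside phosphatase gene AT1G14250 was at 24.6 FPKM in the wild type, 6.20 FPKM in zop1 and 4.14 FPKM in sta1.

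By the 2-fold rule 152 loci were higher and 229 lower in sta1, and 74 and 159 of them were long protein-coding genes. The numbers of higher loci were close to the simulated 149 and 75.8, and those of lower loci above the simulated 148 and 75.02. The simulated scatter came from pairs of mutant libraries that include sta1, so it holds differences of sta1 itself. Closeness to it therefore does not show that the higher loci are unchanged. All 20 loci with the largest changes under the rule were shorter or not protein-coding and at 0 in 1 of the 2 libraries.

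A group of genes differed from wild type in the same direction in all 3 mutants. Among long protein-coding genes 7 were higher: PEPC1, PS2, NAC044 (AT3G01600), a transcription factor gene of the DNA damage response, AT2G04050, the small heat shock protein gene HSP17.6II (AT5G12020), the defensin-like gene AT3G05730 and the uncharacterised AT3G01345. NAC044 was at 1.07 FPKM in the wild type and 3.51, 6.91 and 5.87 FPKM in prp31, zop1 and sta1, AT3G05730 was at 144 against 319, 367 and 363 FPKM, and AT3G01345 was at 0.274 against 2.06, 3.30 and 2.42 FPKM. There were 8 lower genes: PR1, DIC2, PCR1, the seed storage gene CRA1 (AT5G44120), the transcription factor gene ORA47 (AT1G74930), AT5G45630, AT1G07885 and RTFL13. AT5G45630 was at 19.1 FPKM in the wild type and 6.19, 2.93 and 3.34 FPKM in the mutants, and ORA47 was 3.47-fold (2.68 to 4.53), 7.75-fold (5.17 to 12.1) and 4.68-fold (3.41 to 6.53) lower in prp31, zop1 and sta1. RTFL13 was at 10.5 FPKM in the wild type and listed at 0 in the mutants, so its reads could not be recovered and its read support is unknown. AT1G07885 rested on 10 wild type reads, with counting intervals that reach below 1 in zop1 and sta1. Over all loci the counts were 23 higher and 32 lower, and the 10 that ranked highest in each direction were again mostly snoRNA, tRNA, miRNA and short protein-coding loci.

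Simulated unchanged libraries with a shared wild type gave overlaps larger than these, or close to them with the scatter of prp31 and wild type. Both scatters can hold real differences between genotypes. For long protein-coding genes independent lists would share 0.000917 higher and 0.0023 lower genes, but simulated unchanged libraries shared 23.3 and 21.99 on average, and 7.65 and 7.79 with the scatter of prp31 and wild type. The first scatter was wider than that between prp31 and wild type, and the second holds the changes of prp31 itself. Neither simulation can therefore decide whether these changes are shared. With prp31, zop1 or sta1 as the reference, 6, 19 and 13 genes were higher in all 3 other libraries and 8, 30 and 9 lower, numbers that also hold genes changed in that mutant alone. Over all loci the simulated means were 55.5 and 54.8, and independent lists gave 0.00748 and 0.0125. With 1 wild type library the control cannot be split, so part or all of any excess may come from it.

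The changes from the wild type were the most alike in zop1 and sta1. Across 18362 long protein-coding genes their log2 differences had r = 0.63 and a covariance of 0.0624, against 0.35 and 0.0237 for prp31 and zop1 and 0.50 and 0.0314 for prp31 and sta1. The log2 values of sta1 themselves were about as close to those of prp31 (r = 0.98883) as to those of zop1 (r = 0.98872). Unchanged libraries gave r = 0.50 and a covariance of 0.0366, or 0.0214 (maximum 0.0249) with the scatter of prp31 and wild type. The zop1 and sta1 covariance was above both simulated values, while those of prp31 with zop1 and with sta1 lay between them. Of the latter, only that of prp31 and sta1 was above the maximum of 0.0249. The 2-fold rule was met in both zop1 and sta1 by 36 higher and 81 lower genes, where independent lists give 0.443 and 1.51 and the simulations 27.1 and 25.7, or 8.76 and 8.85 with the scatter of prp31 and wild type. BHLH100, bHLH38 and AT2G14247 were among the 36, and ZAT10, DIC2, CAF1a and ERF104 among the 81. prp31 shared 8 higher and 10 lower genes with zop1 and 14 and 17 with sta1, where independent lists give 0.228 and 0.265, and 0.153 and 0.242. These counts were below the simulated 27.1 and 25.7. With the scatter of prp31 and wild type, none was above the simulated maxima of 15 and 19. The counts shared with sta1, 14 and 17, were above the simulated means of 8.76 and 8.85. That scatter holds the changes of prp31 itself, and that of the mutant libraries holds differences between mutants. Neither simulation can therefore decide whether prp31 shares changes with zop1 or sta1. Over all 19240 loci r was 0.43 (prp31 and zop1), 0.46 (prp31 and sta1) and 0.57 (zop1 and sta1), with covariances of 0.0591, 0.0625 and 0.101 against a simulated 0.0779. At all loci 33 were higher and 41 lower in both prp31 and zop1, 38 and 50 in prp31 and sta1, and 69 and 121 in zop1 and sta1, against simulated means of 61.4 and 60.4 and independent overlaps of 0.947 and 1.05, 0.782 and 0.976, and 1.45 and 2.94. Genes are not independent replicates, and no p-value is given.

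**Figure D2:**
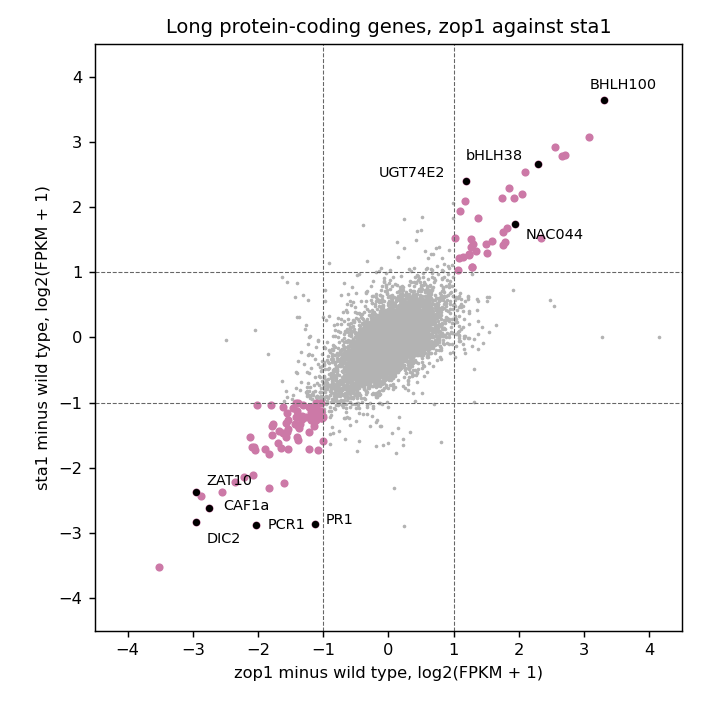
Difference of log2(FPKM + 1) from wild type in zop1 (horizontal axis) and sta1 (vertical axis) for 18362 long protein-coding genes, 1 point per gene, with dashed lines at the 2-fold rule. Coloured points are the 36 genes higher and 81 lower in both, and r across all points is 0.63; black points are named genes among them.

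Direct comparison of the mutants does not use the wild type library. prp31 had 214 loci higher and 168 lower than zop1, and 197 higher and 125 lower than sta1, while zop1 had 139 higher and 122 lower than sta1. Simulated unchanged libraries gave 149 higher and 148 lower loci. Their scatter was that of zop1 and sta1, so the counts of that pair cannot be judged against it. AT4G12490 was at 92.2 FPKM in prp31 against 11.6 FPKM in zop1 and 14.6 FPKM in sta1, and AT4G12500 was at 2.48 and 2.75 FPKM in zop1 and sta1. BHLH100 and AT2G14247 were at 1.299 and 3.36 FPKM in prp31, against 24.96 and 32.2 FPKM in sta1. AT4G13575 was at 5.17 FPKM in zop1 and 32.9 FPKM in sta1, and AT4G33720, a gene of the family of PR1, at 0.978 and 10.7 FPKM. The largest differences over all loci were at snoRNA, tRNA and miRNA loci listed at 0 in 1 library, such as AT2G07762, a tRNA locus at 137 FPKM in prp31 from 3 reads and at 0 in zop1 and sta1.

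In prp31 the cold and dehydration list had a median log2 difference of -0.18 and the abscisic acid list one of -0.24, both below all 10000 matched random lists, with 18 of 23 and 11 of 12 measured members below wild type and no member past 2-fold. RAB18 (AT5G66400), a dehydrin gene, was at 86.2 FPKM in the wild type and 44.4, 43.0 and 42.6 FPKM in prp31, zop1 and sta1. COR15A (AT2G42540), a cold-induced chloroplast protein gene, was at 52.7 against 35.2, 22.7 and 37.8 FPKM. RD29A (AT5G52310) was at 24.8 FPKM in the wild type and at 29.2, 43.8 and 32.9 FPKM in the mutants. The cold list's medians in zop1 and sta1 were -0.11 (percentile 3.26) and -0.01 (38.3, positive at 0.05 under median-of-ratios scaling), with COR15A, ZAT12 (AT5G59820) and ZAT10 in zop1 and RAB18, ZAT12 and ZAT10 in sta1 lower by the 2-fold rule. The abscisic acid list had -0.03 and -0.08 there, inside the 95% range of random lists, and its largest change was in NCED3 (AT3G14440), an abscisic acid synthesis gene, at 31.3 FPKM in the wild type and 20.2, 16.7 and 18.7 FPKM in the mutants.

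The salicylic acid and immune list was low in zop1 (median -0.44, 12 of 15 below wild type) and sta1 (-0.61, 11 of 15), both below all 10000 random lists, and at 0.04 (percentile 94.0) in prp31. With no filter on low values the sta1 median was -0.35. PAD4, a regulator of immune signalling, was at 20.5 FPKM in the wild type, 10.6 FPKM in zop1 and 10.7 FPKM in sta1. WRKY33 (AT2G38470) was at 44.4 against 19.7 and 18.1 FPKM, and PR2 (AT3G57260) was 3.90-fold lower in sta1 (3.34 to 4.57). Members also went the other way: WRKY70 (AT3G56400) was at 50.9 FPKM in the wild type, 128 FPKM in zop1 and 25.1 FPKM in sta1, and CYP71A13 (AT2G30770), a camalexin synthesis gene, was 4.05-fold higher in sta1 (3.38 to 4.86). The jasmonate list had a median of 0.14 in prp31 (percentile 99.9), 0.04 in zop1 and 0.08 in sta1. LOX2 was at 91.1 FPKM in the wild type, 181 FPKM in prp31 and 165 FPKM in sta1, while TAT3 (AT2G24850) was at 4.13 FPKM in the wild type and 1.13 FPKM in sta1.

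The oxidative stress and mitochondrial retrograde list had a median of 0.71 in sta1, above all 10000 random lists, with UGT74E2, UPOX (AT2G21640) and GSTU25 (AT1G17180) past 2-fold. UPOX was at 2.75 FPKM in the wild type and 8.84 FPKM in sta1, and GSTU25 at 5.79 and 15.4 FPKM. The superoxide dismutase genes CSD1 and CSD2 were at 25.3 and 39.2 FPKM in the wild type and 47.0 and 64.7 FPKM in sta1. In prp31 and zop1 the list's medians were 0.10 (percentile 98.9) and 0.06 (81.7). The DNA damage list had medians of 0.08, 0.19 and 0.08 in prp31, zop1 and sta1 (percentiles 95.4, 94.4 and 94.4). Among long protein-coding genes, with 7 members measured, the medians were 0.10, 0.28 and 0.12 (percentiles 96.2, 98.4 and 96.4), so the zop1 value then lay outside the 95% range. SMR7 (AT3G27630), a cell cycle inhibitor gene, was at 0.793 FPKM in the wild type, from 4 reads, and at 2.33, 2.64 and 4.18 FPKM. GMI1 (AT5G24280), a gene induced by DNA breaks, was at 1.16 against 2.28, 2.86 and 3.36 FPKM. Heat shock medians were -0.09, -0.06 and -0.16 and those of the unfolded protein response 0.01 (negative under rescaling to a fixed sum), -0.08 and -0.11, all inside the 95% range. HSP17.6II was 4.74-fold (2.53 to 9.65), 5.24-fold (2.76 to 10.8) and 6.66-fold (3.59 to 13.5) higher in prp31, zop1 and sta1, from 0.490 FPKM, and HSP23.5 (AT5G51440) went from 10.7 to 23.3 FPKM in sta1. The unfolded protein response gene with the largest change, TIN1 (AT5G64510), was at 6.75 FPKM in the wild type and 4.95 FPKM in sta1.

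The spliceosome core list had medians of 0.02, 0.10 and 0.06 in prp31, zop1 and sta1 (percentiles 86.5, 99.1 and 95.9; the prp31 median is negative under rescaling to a fixed sum), with no member past 2-fold. RDM16 (AT1G28060), a spliceosomal protein gene linked to DNA methylation, had the largest change, from 15.6 FPKM to 22.1, 20.9 and 23.2 FPKM. SR splicing factors had medians of -0.05, 0.07 and -0.04, the last positive under median-of-ratios scaling, and the largest change was in RS31A (AT2G46610), from 5.31 to 7.56 FPKM in zop1. The silencing machinery list had medians of -0.06, -0.02 and -0.11, where the zop1 value was positive under rescaling to a fixed sum, and its largest change was in AGO6 (AT2G32940), at 3.32 FPKM in the wild type and 2.07, 3.12 and 1.66 FPKM. DNA demethylation genes had medians of -0.15, -0.02 (positive under rescaling to a fixed sum) and -0.18, inside the 95% range. ROS1 (AT2G36490), the main DNA demethylase gene, was at 11.7 FPKM in the wild type and 6.92 FPKM in prp31, 9.38 FPKM in zop1 and 3.95 FPKM in sta1, which is 1.69-fold (1.59 to 1.80), 1.25-fold (1.17 to 1.33) and 2.96-fold (2.73 to 3.21) lower.

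Among 6 loci known to be silenced, SDC (AT2G17690), an F-box gene held silent by DNA methylation, reached a mean of 1 FPKM, at 1.64 FPKM in the wild type and 3.74, 5.76 and 2.52 FPKM in prp31, zop1 and sta1, or 2.28-fold (1.79 to 2.91), 3.51-fold (2.77 to 4.46) and 1.53-fold (1.17 to 2.01) higher. FWA was at 0.0362 FPKM in the wild type and 0.0817, 0.0986 and 0.0503 FPKM in the mutants. Of 1973 loci listed by a transcript identifier, most of them pseudogenes in the reference, 260 were above 0 in the wild type and 293, 304 and 291 in prp31, zop1 and sta1, and 32, 34, 38 and 37 reached 1 FPKM. The 35 measured ones had medians of 0.01 (negative under rescaling to a fixed sum), -0.04 and -0.07, at percentiles 91.7, 21.7 and 64.0. AT2G04460.1 (chromosome 2, 1547538 to 1548999), a pseudogene, was 6.12-fold (4.40 to 8.71), 5.87-fold (4.18 to 8.44) and 6.82-fold (4.89 to 9.74) higher, from 0.662 FPKM, and AT5G27345.1 went from 0.313 to 1.05, 1.40 and 1.78 FPKM. None of 10 measured Sadhu retrotransposon loci was past 2-fold, with medians of 0.02, -0.14 and -0.04, of which the prp31 and sta1 values changed sign with the scaling.

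Photosynthesis genes were lower in zop1 than in the wild type, with a median of -0.19 (percentile 0.05, 18 of 23 below wild type), and had medians of 0.05 in prp31 and 0.15 in sta1. LHCB1.1, which encodes a light-harvesting protein, was at 2450 FPKM in zop1 and 3372 FPKM in the wild type, while RBCS1B (AT5G38430), a Rubisco small subunit gene, was at 1372 FPKM in the wild type and 2020 FPKM in zop1. Cell cycle genes had medians of 0.22 in zop1 (percentile 99.9, 18 of 21 above wild type), 0.10 in sta1 (99.9) and -0.04 in prp31 (42.9), and CYCB1;1 (AT4G37490), a mitotic cyclin gene, was at 2.48 FPKM in the wild type and 4.19 and 4.21 FPKM in zop1 and sta1. Ribosomal protein genes had medians of 0.07, 0.05 and 0.15, inside the range of equally abundant genes, and RPS10B (AT5G41520) was at 140 FPKM in the wild type and 171 FPKM in sta1. Anthocyanin genes had medians of -0.18 in prp31 (percentile 0.05), 0.01 in zop1 and 0.13 in sta1 (99.0), with UF3GT at 6.03 FPKM in the wild type and 3.42 FPKM in prp31 and TT8 (AT4G09820) at 0.786 and, in zop1, 1.89 FPKM. Root markers had medians of -0.12 in prp31 (percentile 1.95), 0.09 in zop1 and -0.02 in sta1, the last positive under median-of-ratios scaling, and TIP2;3 (AT5G47450), a root aquaporin gene, was at 5.49 FPKM in the wild type and 2.53, 6.15 and 1.46 FPKM. Clock genes had medians of 0.05, 0.01 and -0.08, with the largest change in GRP8 (AT4G39260), from 121 to 73.8 FPKM in zop1. The 3 measured flowering genes had medians of -0.21, 0.19 and -0.19, and SEP3 (AT1G24260) was at 1.81 FPKM in the wild type and 4.46 FPKM in prp31. The 5 measured seed and embryo genes had medians of -0.67, -0.97 and 0.55 (percentiles 0.01, 0.01 and 99.8). With no filter on low values, over 12 genes, the medians were -0.12, -0.0542 and 0.0668, and with a pseudocount of 0.1 the zop1 median was -1.96, so these values depend on the processing. CRA1 was at 6.14 FPKM in the wild type and 1.63, 0.643 and 1.47 FPKM, CRC at 5.37 against 3.02, 0.09 and 0.229 FPKM, and EM6 (AT2G40170) at 2.05 against 1.63, 2.79 and 5.33 FPKM. Over 20 lists and 3 mutants, 17 of 60 medians lay outside the 95% range of random lists, 7 in prp31, 5 in zop1 and 5 in sta1, of which 3 are those of the seed list.

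**Figure D3:**
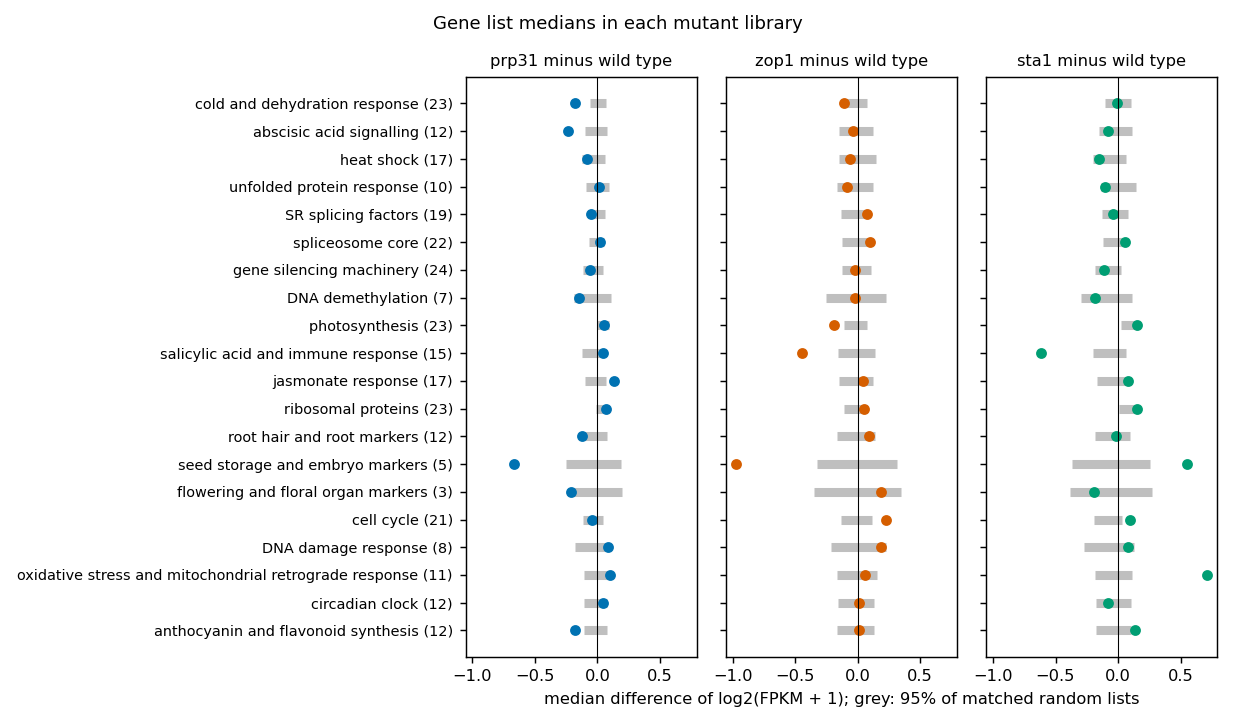
Median difference of log2(FPKM + 1) from wild type (horizontal axis) of 20 gene lists (vertical axis, number of measured genes in brackets) in prp31, zop1 and sta1, with grey bars for the central 95% of 10000 random lists matched on mean expression. The salicylic acid and immune list lies at -0.44 in zop1 and -0.61 in sta1, and the oxidative stress list at 0.71 in sta1.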

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

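The restriction to long protein-coding genes and the simulation with the scatter of prp31 and wild type were chosen after seeing the data. Under the 5 alternatives chosen before the data were examined, 413 recomputed values stayed within 1.5 times the count or within their interval and 31 did not. No list median outside the 95% range and no gene past 2-fold changed sign. The 3 correlations lay between 0.43 and 0.57 under these 5. Both scalings and the absence of a filter left every count within 1.5 times.

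With a pseudocount of 0.1, which gives low genes larger differences, the counts (higher, lower) were 289 and 389 in zop1, 232 and 387 in sta1, 366 and 261 for prp31 over zop1, 305 and 191 for prp31 over sta1 and 236 and 190 for zop1 over sta1, and 48 loci were higher in all 3 mutants. With a mean of at least 5 FPKM, which leaves fewer loci, they were 54 and 40 in prp31, 159 lower in zop1, 92 and 147 in sta1, 12 lower in all 3, 139 and 111 for prp31 over zop1, 127 and 73 for prp31 over sta1 and 87 and 65 for zop1 over sta1. Long protein-coding genes alone gave 38 and 28 in prp31, 110 higher in zop1, 74 higher in sta1, 7 and 8 in all 3, 104 lower for prp31 over zop1, 131 and 60 for prp31 over sta1 and 73 and 65 for zop1 over sta1, with correlations of 0.35 (prp31 and zop1) and 0.63 (zop1 and sta1). Many of the loci left out there rested on few reads: of their changes with recovered reads, 65.9% held under 10 reads in the 2 libraries together. Where reads were not recovered, the read support is unknown.

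The salicylic acid and immune median in sta1 was -0.76 with a pseudocount of 0.1, -0.35 with no filter and -0.89 at a mean of 5 FPKM. The seed and embryo medians with no filter were -0.12, -0.0542 and 0.0668 in prp31, zop1 and sta1, since 12 genes then enter in place of 5, and -1.96 in zop1 with a pseudocount of 0.1. The cell cycle median of prp31, inside the range of random lists, was 0.0501 at a mean of 5 FPKM, and the cause was not tested. Of 2049 recomputed single-gene differences 51 moved past their counting interval, 50 of them to a larger size. The class of transcript-identifier loci has no value among long protein-coding genes. No paired analysis was possible because each genotype has 1 library. Loci with few reads have wide counting intervals: PDF1.2A, with 1 read in the wild type and 7 in zop1, had a fold of 8.47 with an interval of 1.09 to 382.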

Other observations

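The gene lists of this part were chosen after the largest changes had been seen, and leave those genes out; the tests of root tissue, of the time of day and of differences between mutants were chosen only after results they bear on were known. Of 14 measured phosphate-starvation genes other than PEPC1 and PS2, 14 lay above wild type in prp31 (median log2 difference 0.94), 13 in zop1 (0.44) and 11 in sta1 (0.53), some by very little. The 2-fold rule was met by 6 in prp31, and by 0 in zop1 and 0 in sta1. SPX1, a phosphate sensor gene, was at 24.9 FPKM in the wild type and 69.9, 44.9 and 41.3 FPKM in prp31, zop1 and sta1, the non-coding IPS1 at 22.8 against 57.1, 30.7 and 33.4 FPKM, and SQD2, of sulfolipid synthesis, at 39.2 against 84.3, 58.1 and 65.9 FPKM. All 3 medians lay at percentile 100 of matched random lists. The 3 comparisons share 1 wild type library, so they are not independent. Without that library, 13 of 14 genes were lower in zop1 than in prp31 (median -0.36) and 13 in sta1 (-0.43), a part that the wild type library cannot give. For the part common to the mutants a wild type library low in these genes stays open, and for both parts so do the supply of the medium and an effect of the mutations, as untested.

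The median of further iron-deficiency genes was high in zop1 and sta1, at 0.39 and 0.35 over 15 measured genes, and low in prp31 (-0.12, percentile 0.615). Of these genes 10 in zop1 and 11 in sta1 lay above wild type, and 2 in each met the 2-fold rule. Without the wild type library, 11 were higher in zop1 than in prp31 (median 0.58) and 14 in sta1 (0.63), both at percentile 100. OPT3, of iron transport in the phloem, was at 24.99 FPKM in the wild type and 73.0 and 62.7 FPKM in zop1 and sta1, BTS, a negative regulator of the response, at 15.6 against 30.9 and 29.1 FPKM, and ORG1 at 16.5 against 48.3 and 46.2 FPKM. The iron uptake genes IRT1 (467 FPKM in the wild type, 368, 325 and 383 FPKM in prp31, zop1 and sta1) and FRO2 (97.2 against 58.5, 61.6 and 71.0 FPKM) were lower in all 3 mutants. IRT2 (3.39 against 3.06, 7.08 and 5.34 FPKM) was higher in zop1 and sta1. The lower percentile of zop1 and sta1 against the wild type was 100, as a wider response would need, but members thus went both ways. A larger share of root tissue cannot be told apart from such a response: the root list had medians of 0.0925 in zop1 and -0.02 in sta1 (positive under median-of-ratios scaling), but its members went both ways, with 7 above and 5 below wild type in zop1 and 4 above and 8 below in sta1, and 3 and 1 of 12 reached the median of the iron list. The root hair genes PRP3 and EXPA7 were at 89.1 and 4.71 FPKM in the wild type, 152 and 6.73 FPKM in zop1 and 127 and 5.06 FPKM in sta1, and TIP2;3 was at 5.49 against 6.15 and 1.46 FPKM. The 6 iron storage genes had medians of -0.21, -0.11 and -0.23 in prp31, zop1 and sta1. An effect of the mutations on iron supply and a difference in the medium both stay open, as untested.

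Genes of early stress and touch other than those named above were lower in zop1 and sta1, with 26 of 27 measured genes below wild type in each and medians of -0.76 and -0.77, and at -0.28 in prp31, below all random lists in each mutant. SZF1, a zinc-finger gene, was at 22.5 FPKM in the wild type and 4.68 and 6.07 FPKM in zop1 and sta1, ERF5 at 17.2 against 3.91 and 4.57 FPKM and WRKY40 at 4.84 against 1.17 and 1.32 FPKM. A time of day at harvest that shifts clock genes as much as these is argued against: the median size of change of 12 clock genes was at most 0.17 in zop1 and sta1, and the largest was 0.71 (GRP8 in zop1). A smaller difference in the time of harvest was not tested and stays open. Handling of the wild type seedlings alone is argued against for the part by which zop1 and sta1 lay below prp31, since the medians without the wild type library were -0.52 and -0.56, below all random lists. Handling of the prp31, zop1 or sta1 seedlings was not tested and stays open for that part, as does an effect of the mutations. For the rest of the medians of -0.76 and -0.77, handling and an effect of the mutations cannot be told apart with 1 wild type library.

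There were 15 long protein-coding genes past 2-fold in all 3 mutants, and between 14 and 49 with each mutant in turn as the reference, but the latter numbers also hold genes changed in the reference mutant alone and do not measure scatter. Scatter of the libraries, a wild type library that differs from other wild type plants and an effect of the mutations cannot be told apart here, since no genotype has a second library. No gathering of changed genes within 1 Mb of the mutated genes was seen: the highest ratio over the mutants, of the share changed within 1 Mb to the share elsewhere, was 1.13. Wider windows were not examined. LPLAT2 (chromosome 1, 23375877 to 23378355), past 2-fold in prp31 only, lies on the chromosome of PRP31 outside that window. The shares within 1 Mb rest on few changed genes, 1 of 253 in prp31, 5 of 288 in zop1 and 2 of 232 in sta1, so these ratios are imprecise.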
